A study of Caenorhabditis briggsae with 13 samples.

How the data were processed

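Total RNA from staged embryos of Caenorhabditis briggsae, a nematode related to C. elegans, was measured on 13 one-colour arrays labelled with the dye Cy3. Per the labels, each sample was RNA from 50 embryos of strain AF16. The RNA was amplified in successive rounds of in vitro transcription, labelled, and hybridised to a 44k array of oligonucleotide probes designed for this species. Per the labels, replicates of a stage were separate biological samples, and the 4-cell and 95-cell stages have 2 arrays because an amplification was poor. The stages were the 4-cell, 28-cell, 55-cell, 95-cell and 190-cell embryo, at 0, 55, 80, 120 and 160 min after the 4-cell stage. Stages were taken from the sample titles. The stage tag of 4 arrays (28-cell B, 55-cell A, 95-cell A and 190-cell B) read 4-cell and contradicted the title. The titles were used because their numbers per stage match those in the protocol, and the counts were recomputed without these 4 arrays.

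Spots were quantified with Agilent Feature Extraction, per the submitters' processing notes, in version 9.5.3.1, per the file headers. The deposited intensity of a spot is its processed signal, from which the scanner software had subtracted background and a spatial trend. No scaling between arrays was applied to it: the 75th percentile of the intensity ranged from 234.8 to 546.6. The deposited series table held the same intensity, equal to the scanner output to every digit on 12 arrays (relative tolerance 1e-06). The scanner output under 28-cell C was a byte-for-byte copy of that of 190-cell C, whereas its column in the series table held other values. Series-table values were therefore used for all 13 arrays. Detection flags, slide and scan date of 28-cell C were not used here, so that filters on detection rest on 12 arrays. The other columns used, per the file headers, were flags for spots well above background, saturated or non-uniform, and the median brightness of spot and local background. No column of another series was present (0 columns).

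The arrays carried 42034 gene probes for 19528 genes, with 1 spot per probe. They were named by gene identifier and by a letter from A (best ranked) to E. 207 probes with an outlier flag on any array were left out, control spots were left out, and saturated spots were kept. Values were log2 intensity minus the array's own 75th percentile over all gene probes. The plan named probes detected on all arrays as the scaling set if fewer probes were detected than not, without saying on how many arrays. That was so on both 4-cell arrays (40.6% and 39.8% well above background) and on 95-cell A (47.5%), and on no other array with flags. Scaling on all gene probes was kept as the main setting, and the other scaling is given as an alternative. A probe was kept when it was well above background on every array of at least 1 stage, which left 24781 probes. A gene's value was the mean of its kept probes. 13443 genes were tested, 4649 of them with a single probe and 8794 with several.

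Comparisons were made with limma 3.58.1 in R 4.3.3 on all 13 arrays (lmFit, eBayes), so that all stages shared an estimate of the spread. A moderated F-test compared the 5 stages, and two-sided moderated tests compared successive stages and the 190-cell with the 4-cell stage. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Calls were also made relative to the median change of all tested genes, because a constant added to an array moves every gene of it alike. The median places as many tested genes above as below it. The split of these calls therefore does not tell whether rises or falls prevailed. Where no probe of a gene was well above background on any array of a stage, the fold was given as a bound. The brighter stage's mean was then set against the dimmer stage's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. A gene counted as peaking between the ends of the series when the same middle stage was called higher than both the 4-cell and the 190-cell stage, and as having a trough when it was called lower than both. Both counts were also made on simulated genes that follow their best monotone course. These profile counts were chosen after the data were examined.

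The same fit was tested on simulated data with the real means and spreads of 13443 genes and 200 genes moved in 1 stage. For 190-cell vs 4-cell it recovered 7.58% of genes planted at 2-fold, 59.7% at 4-fold and 92.5% at 8-fold, with 6 false calls. For 55-cell vs 28-cell the shares were 9.09%, 86.6% and 97.0%, with 10 false calls, and for 190-cell vs 95-cell 4.55%, 56.7% and 97.0%, with 5. No planted gene was called in the wrong direction. Changes near 2-fold were therefore often below what these numbers of arrays resolve in such a simulation, in which few genes change.

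None of the 12 arrays with their own scanner output shared a slide with another, so no fit with slide as a block was made. 9 arrays were scanned on a first date and 3 (55-cell C, 95-cell B and 190-cell C) on a second. The alternatives fixed before the data were examined were quantile normalisation, the 75th percentile over probes detected on all arrays, normexp background correction (offset 50), and no or a stricter filter on dim probes. They also included the A probe or the brightest probe alone, the 2 compared stages alone, the replicate letter or scan date as a block, array weights, a log2 change of at least 1, the contradictory tags and leaving out each array. Normexp was run on median instead of mean spot brightness, since mean brightness was not used here. Scaling on spiked-in control RNA (6 probes), centring on the median gene, a common floor, and the first scan date alone were added after the data were examined. Probes are identified by WormBase gene numbers only. The files do not pair these with gene symbols, and 0 of them matched the reference table used here. The planned gene lists, named genes and comparison of neighbours on chromosomes were not analysed here. Instead, under the rule fixed for this case, 2 identifiers that rose and 2 that fell are given for 190-cell vs 4-cell. They are those with the largest changes among called genes that met 3 conditions. At least 1 kept probe was well above background on every array of each of both stages. The stages' arrays did not overlap, and all kept probes changed the same way.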

Results

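The series followed gene expression through early cleavage and gastrulation-stage embryos of C. briggsae, with 2 arrays at the 4-cell stage, 3 at 28 cells, 3 at 55 cells, 2 at 95 cells and 3 at 190 cells. Each array measured RNA from 50 embryos, so that cell types within an embryo were not resolved. The number of arrays limits the precision of every comparison. Across kept probes, arrays of 1 stage correlated with r between 0.936 and 0.990, and arrays of different stages with r between 0.631 and 0.960. The 4-cell pair had r = 0.990. These correlations are across probes, which are not independent replicates.

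The stages separated in developmental order. The first principal component held 48.6% of the variance between arrays and ran from -165 on a 4-cell array to 134 on a 190-cell array. The second component held 32.9% and set the 28-cell and 55-cell stages apart from both the first and the last stages. Within the 28-cell, 55-cell, 95-cell and 190-cell stages, the arrays of the second scan date and 28-cell C lay furthest along the first component.

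**Figure D1:**
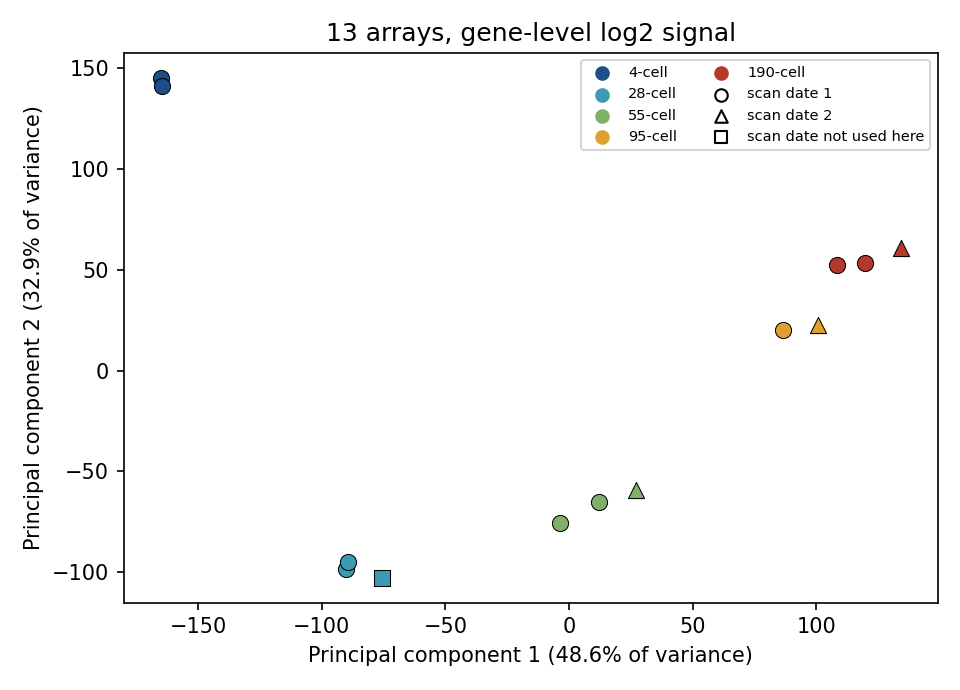
Each point is 1 of 13 arrays on the first (48.6% of variance) and second (32.9%) principal components of gene-level log2 signal; colours mark the stage and symbols the scan date. The 2 4-cell arrays lie at -165 on the first component and the 3 190-cell arrays between 108 and 134.

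Fewer genes were detected at the 4-cell stage than later. At least 1 probe was well above background on both 4-cell arrays for 9208 genes. On the 28-cell arrays with flags the number was 11776 genes, on the 55-cell arrays 11975, on the 95-cell arrays 10860 and on the 190-cell arrays 12184. Among the arrays of the first scan date the numbers were 9208, 11776, 11994, 10916 (1 array) and 12201. 8496 genes were detected at every stage. 2654 genes were detected on every 190-cell array and on neither 4-cell array, against 73 genes with the opposite pattern. On the arrays of the first scan date, without the more sensitive 190-cell C, these numbers were 2665 and 201. The lowest signal well above background was 17.5 and 25.7 on the 4-cell arrays, against 10.3 and 10.6 on 190-cell A and B. Part of this contrast may therefore come from sensitivity. Detection also moved with scan date: the 3 arrays of the second date had 64.9% to 67.9% of probes well above background, and the 9 of the first date 39.8% to 56.5%.

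**Figure D2:**
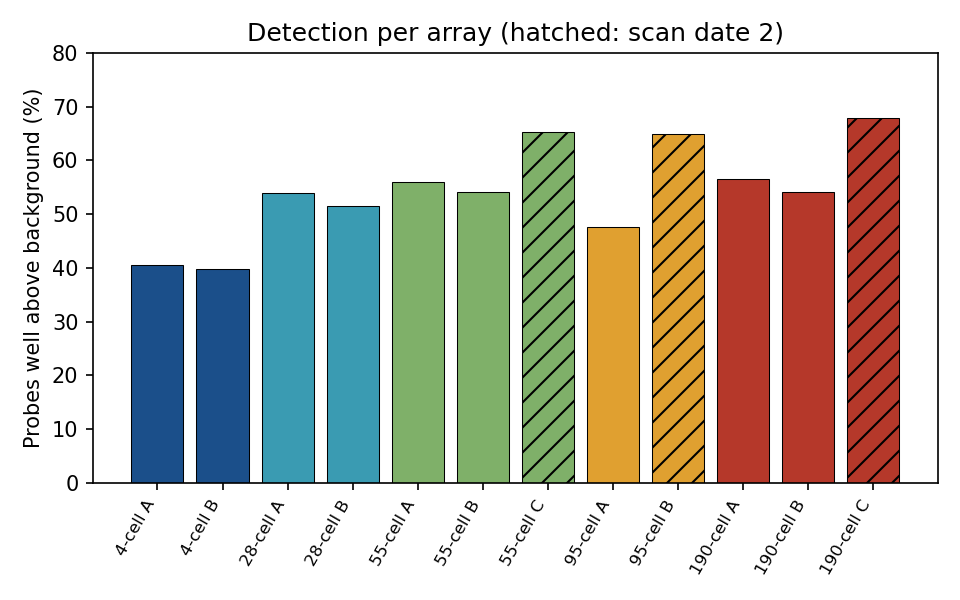
Bars give the percentage of 42034 probes well above background on each of the 12 arrays with their own flags; colours mark stages and hatching the second scan date. The 4-cell arrays stand at 40.6% and 39.8%, and every other array at 47.5% or more.

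The first question was which genes changed at all over the course. Of 13443 genes tested, 10360 (77.1%) differed between the 5 stages (limma moderated F-test). Among these, 4301 genes had their highest mean at the 4-cell stage, 2174 at 28 cells, 997 at 55 cells, 814 at 95 cells and 2074 at 190 cells. The mean was lowest at the 4-cell stage for 2871 genes, at 28 cells for 2258 and at 190 cells for 2414. These rankings depended on scaling: with arrays scaled on probes detected on all of them, 1916 of 10906 called genes were highest at the 4-cell stage, 3182 at 28 cells and 2875 at 190 cells, and 6519 were lowest at the 4-cell stage. Spike-in scaling, also without 28-cell C, put 1067 of 5870 highest and 3304 lowest at the 4-cell stage. With scan date as a block, without 28-cell C, 10781 genes were called, and 10098 within the first scan date. The second date held 1 array of each of 3 stages and allowed no test.

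The comparison of the last with the first stage asked how the transcript population of the 4-cell embryo differed from that of the 190-cell embryo. 8440 genes changed, of which 3579 were higher at 190 cells and 4861 lower. With genes that were not above background at the dimmer stage set to their bound, the median called rise was 3.73-fold and the median called fall 3.83-fold, and 1706 genes rose and 2334 fell by at least 4-fold. Fitted values, which take signals at background as levels, gave 2364 and 2437 genes. The balance of rises and falls depended on scaling. The median change of all genes was -0.45 on the log2 scale in the main scaling, 0.84 when arrays were scaled on probes detected on all of them, and 0.55 with spike-in scaling. The last 2 scalings gave 6421 rises with 2160 falls and 3607 rises with 1288 falls. Relative to the median change, 4283 genes lay above and 3611 below it in the main scaling, 4322 and 3775 with scaling on detected probes, and 2852 and 1778 with spike-in scaling. A split near even is largely set by the use of the median, and does not decide whether rises or falls prevailed. With scan date as a block 8877 genes were called, and within the first scan date 8400.

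WBGene00041531 and WBGene00031211 had the largest falls in gene means of the 4095 genes that met the naming rule in that direction. The files do not pair these numbers with gene symbols. WBGene00041531 fell from the 4-cell to the 190-cell stage, with a fitted log2 change of -11.37 (SE 0.318, limma adjusted p = 3.23e-10). Its A probe was well above background on 0 of 3 arrays at 190 cells, and its B probe, above background on every array of both stages, changed by -10.91. The fitted change was -9.40 with a common floor and -8.41 with normexp. Under both settings WBGene00031211 fell further (-10.10 and -8.81). The level of WBGene00041531 over the 75th percentile was 5.86 ± 0.0019 (SD, n = 2) at 4 cells, 0.92 ± 0.27 (n = 3) at 28 cells, -1.06 ± 0.20 (n = 3) at 55 cells, -2.98 ± 0.25 (n = 2) at 95 cells and -5.51 ± 0.50 (n = 3) at 190 cells, all on the log2 scale. Over its 3 probes, all above background on these arrays, WBGene00031211 fell 1267-fold (log2 change -10.31, SE 0.295, limma adjusted p = 3.28e-10). It started at 6.75 ± 0.18 (SD, n = 2), stood at -0.75 ± 0.092 (n = 3) by 28 cells, and reached -3.55 ± 0.50 (n = 3) at 190 cells.

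WBGene00026844 and WBGene00028436 had the largest rises in gene means of the 1507 genes that met the rule. WBGene00026844 rose with a fitted log2 change of 9.69 (SE 0.573, limma adjusted p = 1.63e-08). Its A probe was not well above background on either 4-cell array, and its B probe, above background on all arrays of both stages, changed by 8.80. The order of these genes depended on the setting. With normexp the changes were 7.10 for WBGene00026844 and 8.17 for WBGene00028436, and with a common floor 8.57 and 9.03. With the brightest probe alone they were 8.80 and 8.71. The level of WBGene00026844 was -4.50 ± 0.27 (SD, n = 2) at 4 cells, -3.90 ± 0.86 (n = 3) at 28 cells and -1.66 ± 1.07 (n = 3) at 55 cells. It was 3.40 ± 0.32 (n = 2) at 95 cells and 5.19 ± 0.34 (n = 3) at 190 cells. WBGene00028436 rose 522-fold (log2 change 9.03, SE 0.304, limma adjusted p = 4.76e-10). It stood at -2.004 ± 0.39 (SD, n = 2) at 4 cells and at 6.85 ± 0.27 (n = 3) already at 28 cells, and then between 6.94 and 7.03 at the later stages. A spot was saturated on 1 of 3 arrays at 55 cells and on 1 of 2 at 95 cells, so those levels are lower limits. None was saturated at 4 or 190 cells, or on the 2 arrays with flags at 28 cells. The mean at 190 cells (7.02) was close to those of the stages with a saturated spot, so signals just below saturation are not excluded there. The share of all tested genes with no overlap between the arrays of these stages was 76.9%, where chance gives 20% for 3 arrays against 2.

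Many rises started from a level that was not well above background. 1750 genes rose while none of their kept probes was well above background on either 4-cell array and at least 1 was on every 190-cell array. The number was 1277 with no filter on dim probes, 1027 with a common floor and 804 with normexp. For 1389 of them a bound over 1 could be given, with a median of at least 3.46-fold and a maximum of at least 853-fold. 633 of these rose at least 4-fold. In the other direction 82 genes fell until no kept probe was well above background on any 190-cell array, with a median of at least 11.5-fold and a maximum of at least 1350-fold. The number was 73 with no filter on dim probes, when all probes of a gene count. The count of 82 genes rested on 190-cell C, the most sensitive array of that stage, and was 205 without it.

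The earliest interval held the most changes and was also the longest, so counts per interval are not rates. Between 4 and 28 cells, over 55 min, 7500 genes changed, 3377 upwards and 4123 downwards. 1682 of the risers had no kept probe above background on either 4-cell array. With such genes at their bound the median called rise was 3.50-fold and the median called fall 4.13-fold, 1535 genes rose and 2131 fell by at least 4-fold, and 519 rose by at least 16-fold. The median gene moved by -0.18 in the main scaling, 1.02 with scaling on detected probes and 0.54 with spike-ins. The last 2 gave 6988 rises with 2121 falls and 2568 rises with 1071 falls. Relative to the median change, 3636 genes lay above and 3701 below in the main scaling, and 1971 and 1706 with spike-in scaling. 7592 genes were called with scan date as a block and 7410 within the first date.

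Between 28 and 55 cells, 3724 genes changed, 1692 upwards and 2032 downwards, with a median rise of 2.44-fold and a median fall of 2.93-fold, bounds included. The median change of all genes was -0.098, and 1983 genes lay above and 1793 below it (348 and 330 with spike-in scaling). At least 4-fold rises then numbered 368 and falls 595. Spike-in scaling called 708 genes, 417 of them upwards. The block for scan date gave 3991 genes and the first scan date alone 3173. These fits, that with spike-in scaling included, were without 28-cell C.

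Between 55 and 95 cells, 2654 genes changed, 993 upwards and 1661 downwards, with a median rise of 3.08-fold and a median fall of 3.18-fold, bounds included. Spike-in scaling called 523 genes, no filter on dim probes 1492, and the fit without the 4 arrays with contradictory tags, which leaves a single 95-cell array, 968. Relative to the median change of -0.19 the called genes were 1316 above and 1274 below. Spike-in scaling cannot turn a gene's direction relative to the median, but fewer genes passed with it, 214 above and 316 below. With each array centred on its median gene, 1367 rose and 1279 fell. 3211 genes were called with scan date as a block and 1992 within the first date, where the 95-cell stage had 1 array. Leaving out a 95-cell array gave 1495 genes without 95-cell A and 1433 without 95-cell B.

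The last interval held the fewest changes. From 95 to 190 cells, 991 genes changed, 633 upwards and 358 downwards, with a median rise of 3.96-fold and a median fall of 3.31-fold, bounds included. The count was 84 genes with spike-in scaling, 276 with only probes detected on all arrays and 356 without the 4 arrays with contradictory tags, again with a single 95-cell array. The median change of all genes was 0.080, and 565 genes lay above and 414 below it (77 and 28 with spike-in scaling). Normexp background correction gave 595 rises and 202 falls. The scan-date block gave 1378 genes, and the first scan date alone 484 with a single 95-cell array. Without 95-cell A the count was 417 genes and without 95-cell B 416.

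**Figure D3:**
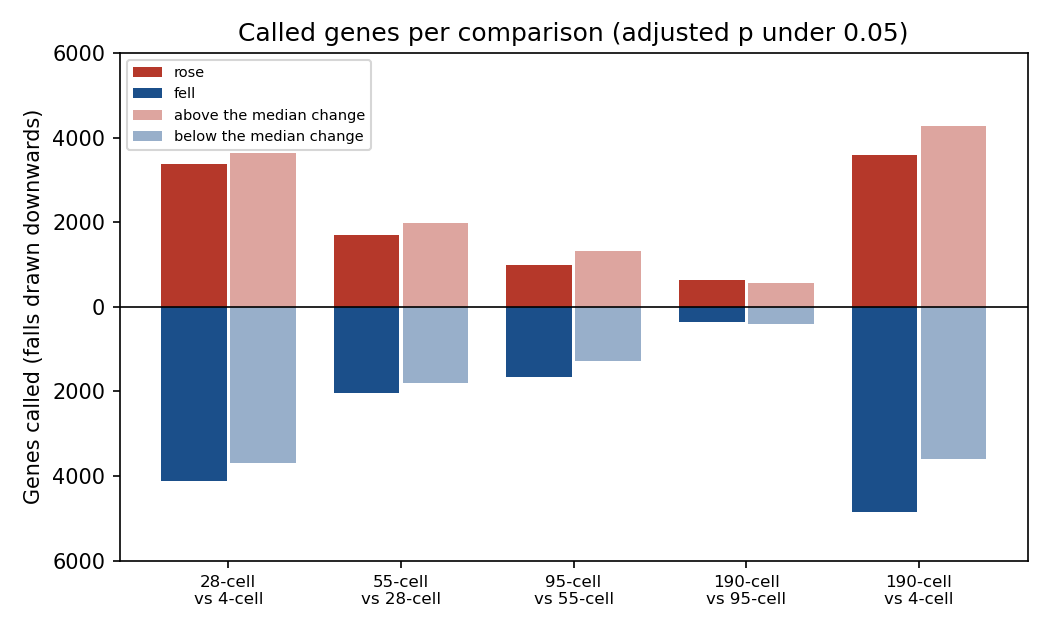
Bars give called genes per comparison (limma, adjusted p under 0.05), with rises above and falls below 0; solid bars count changes in the main scaling and pale bars changes relative to the median change of all 13443 genes. Calls between successive stages decline from 7500 to 991, and the pale bars of 28-cell vs 4-cell number 3636 above and 3701 below. The median places as many tested genes above as below it, so the pale bars do not show which direction prevailed.

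In the main scaling, the time course placed most declines early. Of the 4861 genes lower at 190 than at 4 cells, 3132 (64.4%) were already called lower at 28 cells, 625 were first called at 55 cells, 668 at 95 cells and 436 at 190 cells. Of the 3579 genes that rose, 1996 (55.8%) were called higher at 28 cells, and 622, 447 and 514 were first called at the next 3 stages. Sizes were followed in genes above background on every array with flags of both end stages. Among 2027 such genes that fell by at least 4-fold, the median log2 change from the 4-cell stage was -2.55 at 28 cells, -2.86 at 55 cells, -2.98 at 95 cells and -3.03 at 190 cells. A median of 72.5% of the final log2 fall was reached at 28 cells. Among 930 that rose by at least 4-fold the medians were 1.76, 2.58, 3.03 and 3.27, and a median of 55.4% of the final rise was reached at 28 cells. Falls and rises were not tested against each other for timing. All of these changes share the 4-cell arrays and were followed in the main scaling only. The median 28-cell vs 4-cell change of all genes was -0.18 there, 1.02 with scaling on detected probes and 0.54 with spike-ins. Which genes count as falling or rising, and the shares reached at 28 cells, may therefore depend on scaling.

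A set of genes was higher in the middle of the series than at its ends. 2106 genes were called higher at a middle stage than at both the 4-cell and the 190-cell stage. Their highest middle stage was 28 cells for 1470 genes, 55 cells for 583 and 95 cells for 53. 1165 of the genes had no kept probe above background at 1 or both ends, and only 200 had none at both, so most were detected at an end. With such ends at their bound the median peak stood 2.92-fold above the higher of both ends. At 28 cells 1766 genes were higher than both ends, where independent lists of the same sizes would share 971; part of the excess may come from the 28-cell arrays that both comparisons share. Where every gene was simulated on its best monotone course with the real spread, 20 simulations gave at most 101 peaking genes, and with no effect in any gene 0. The simulated noise was independent between genes and arrays, with no deviation shared across an array and no scaling error. These limits therefore do not cover such effects. The count was 1090 with spike-in scaling, 3023 with scaling on detected probes, 701 with only probes detected on all arrays, 2049 within the first scan date and 2323 with scan date as a block.

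Another 1674 genes had a trough at a middle stage, at 28 cells in 1149, at 55 cells in 449 and at 95 cells in 76. The median trough was 2.28-fold below the lower of both ends, bounds included. At 28 cells 1339 genes were lower than both ends, where independent lists would share 1030. At 55 cells these numbers were 767 and 737, and at 95 cells 114 and 236, so the excess lay at 28 cells. As for peaks, the comparisons of a stage share its arrays. The monotone simulations, again with independent noise, gave at most 98 genes with a trough, and those with no effect 0. This count depended on scaling: 913 genes had a trough with scaling on detected probes and 163 with spike-in scaling. It was 1586 within the first scan date and 1876 with the block.

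**Figure D4:**
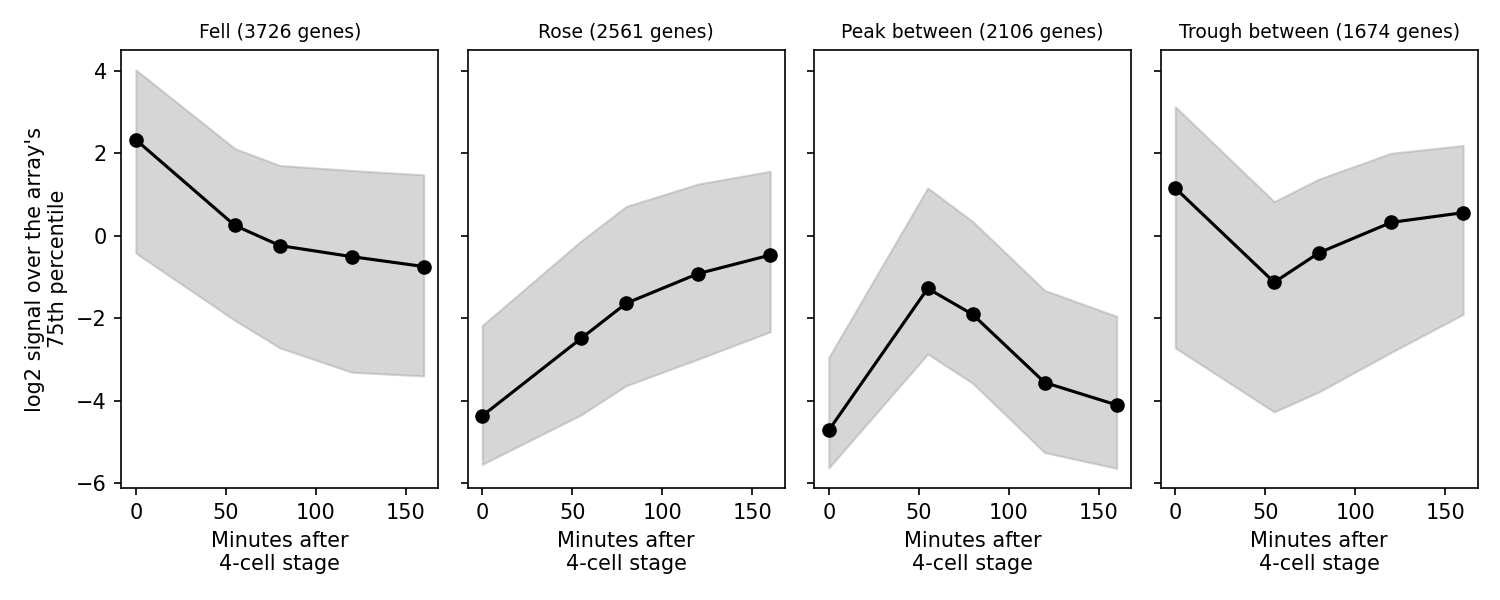
Lines give the median and grey bands the interquartile range of stage means (log2 signal over the array's 75th percentile) against minutes after the 4-cell stage, for 3726 genes that fell and 2561 that rose from 4 to 190 cells without a peak or trough, 2106 with a peak between and 1674 with a trough between. The peaking genes go from a median of -4.72 at the 4-cell stage to -1.28 at 28 cells and -4.11 at 190 cells.

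Different probes of a gene were compared as a check within the arrays. For 8540 genes with a kept A and B probe, the log2 changes from 4 to 190 cells had r = 0.902 across genes, and those from 4 to 28 cells 0.894. Of 5140 genes called by each of the 2 probes alone for 190-cell vs 4-cell, 5044 had the same direction and 96 opposite directions. For 28-cell vs 4-cell the numbers were 4703 called by each, 4640 alike and 63 opposite. The later successive comparisons had at most 2 genes with opposite calls.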

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

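Spike-in scaling, centring on the median gene, a common floor, the first scan date alone and all profile counts were chosen after the data were examined. Each count was recomputed under 16 or 17 alternatives and with each of 13 arrays left out. The following moved by over 1.5 times. Keeping only probes detected on all arrays, which tests fewer genes, gave 6456 genes over the 5 stages, 4961 for 28-cell vs 4-cell (1338 up), 2144 for 55 vs 28, 1078 for 95 vs 55, 276 for 190 vs 95 and 5556 for 190 vs 4 (1475 up). It left 701 peaking genes and, by construction, 0 that rose from or fell to not above background. Spike-in scaling, without 28-cell C, gave 5870, 3639, 708, 523, 84 and 4895 in the same order, 1090 peaks and 163 troughs. Before any scaling, spike-in signals had a median SD of 0.689 (log2) between arrays. This SD includes differences in brightness of whole arrays, so it does not measure the error of the scaling. No filter on dim probes gave 2454, 1492 and 476 for the comparisons of 55 vs 28, 95 vs 55 and 190 vs 95. Without the 4 arrays with contradictory tags these 3 successive comparisons gave 2394, 968 and 356; the last 2 rest on a single 95-cell array, as when 95-cell A alone is left out (1495 and 417). For 190 vs 95, array weights gave 1614, the 2 stages alone 503 and the first scan date alone 484. Troughs numbered 913 with scaling on detected probes and 2548 with array weights. Rises from not above background numbered 804 with normexp and 1027 with a common floor, and falls to it 205 on the first scan date. The cause of the other differences was not tested. Of settings within 1.5 times, no filter on dim probes gave 2884 rises and 8297 falls for 190 vs 4. Normexp gave 2370 rises and 6128 falls for 190 vs 4, and median centring 2748 rises and 5712 falls for 28 vs 4.

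Leaving out 1 array gave 1433 to 2881 genes for 95 vs 55 and 416 to 1165 for 190 vs 95, the lowest without a 95-cell array, when the lone array is assumed to vary like other stages. For falls to not above background the range was 78 to 205, the highest without 190-cell C. The other counts stayed within 1.5 times. The 4 named identifiers kept their direction and call in the 16 alternatives and 13 omissions run for them.

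No consistent pairing by replicate letter was seen: 10 of 23 same-letter pairs had deviations correlated over 0.1 (range -0.498 to 0.530), and 5 of 13 arrays correlated best with their own letter. A pairing is not excluded, since 95-cell B, scanned on the second date, had r of -0.498 to -0.194 with the other B arrays. Among A arrays, those of 28, 55 and 95 cells had r of 0.339 to 0.392. That of 4 cells had -0.278 to -0.241 with them. The letter as a replicate block gave 10936 genes over the 5 stages, 7529, 4082, 3312 and 1049 for successive comparisons and 8434 for 190 vs 4. The slide block was not run, since none of the arrays with a known slide shared it with another. Gene lists and chromosomal neighbours were not run either, for want of a match of identifiers. The series table as source equals the main values. Dim genes limit folds, since signals at the detection limit give bounds.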

Other observations

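The tests of 4-cell detection, of scaling, of near-identical copies and of later staging were chosen after the results were seen; the other tests were fixed before.

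Genes with consecutive WormBase numbers had similar stage profiles. Among 10360 genes that differed between stages, 6332 pairs had numbers that differ by 1, and the median Pearson r of their 5 stage means was 0.459. In shuffled orders it was 0.0186 at the median and 0.071 at the highest, and 0.001 of the 1000 orders, the observed one included, reached it (permutation, the smallest share these can give). The median r declined to 0.244 at a difference of 2, 0.193 at 3, 0.118 at 10 and 0.042 at 100. 19.3% of consecutive pairs had r over 0.9, against 8.61% in shuffled orders.

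Spots of consecutive genes were not printed close together, as the ratio of their median distance to that of random pairs was 1.02. Near-identical copies in 25% of the pairs or fewer would not account for it: without the 25% of pairs with the highest r, the observed median was 0.112, which is 0.0937 above the median of whole shuffled orders and above the highest of them. Gene order along the genome, cross-hybridisation in larger families of tandem copies, and 1 gene annotated under 2 numbers were not tested and stay open, since gene positions and sequences were not analysed here.

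The 4-cell arrays had the fewest probes above background, and the scaling set whether rises or falls prevailed. Higher background on these arrays as the only cause would end the gap at a common signal limit of 28.08. The higher 4-cell share stayed 5.65 percentage points below the lowest other array of the first scan date. The gap narrowed, however. The 4-cell shares went from 40.6% and 39.8% to 37.5% and 39.7%, and those of 190-cell A and B from 56.5% and 54.1% to 46.8% and 45.3%. A contribution of background to the gap therefore stays open. Less labelled RNA would lower the bright probes too, but the 90th percentile of the signal was 1.33 times that of the others while the median was 0.406 times. With scaling on probes detected on all arrays 74.8% of the 190-cell vs 4-cell calls rose, against 42.4% in the main scaling, so the majority direction may reflect the choice of scale. The brightest 1% of probes held 25.3% of the signal at 4 cells and 28.6% on the others, so the brightest probes took no larger share there. A difference in the transcript population of the stage and uneven amplification of its RNA were not tested, and both stay open.

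The 3 arrays of the second scan date deviated from their stage means together, and 28-cell C with them (r 0.330 to 0.530 among the 4). A different background floor would confine this to dim genes, but the mean correlation was 0.608 among the brighter 6722 genes and 0.402 among the dimmer 6721. Later staging of these embryos would move them along the course, and the arrays lay furthest along the first principal component of their stages. The deviation of 55-cell C had r = 0.365 with the change from 28 to 95 cells, and that of 95-cell B 0.0154 with the change from 55 to 190 cells, so these arrays do not decide it. The highest r with the course around another stage was 0.295 for 55-cell C and 0.029 for 95-cell B. For 28-cell C, r was 0.0965 along its own course and 0.169 along another, so specificity for the own stage was low or absent. Late changes called on the first date alone, where scan date cannot differ, mostly went the same way on the second date. For 95-cell vs 55-cell the share was 96.2% of such genes (all tested genes 80.1%). For 190-cell vs 95-cell it was 96.2% (all tested genes 72.5%). The 95-cell stage had 1 array on each date. These changes therefore recurred on the second date. Scan date as a cause of calls that mix arrays of both dates was not tested this way. The genes were chosen among the 13443 kept over both dates, whereas the counts given above for the first date alone chose probes on that date's arrays. Later staging and a shared batch of amplification, labelling or scanning stay open as the source of the shared deviation.

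For 55-cell vs 28-cell, 10 splits of the 6 arrays are too few for a share under 0.05: the real split gave 3724 genes, the highest of the others 87, and 1 split reached the real value. For the 5 stages, 1 of 100 groupings of the 13 arrays, the real one, gave 10360 genes, and the highest other gave 5198, so chance can be excluded at that level.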
